A study of Mus musculus with 6 samples.

How the data were processed

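Total RNA of 6 mouse samples was amplified to biotin-labelled cRNA and hybridised to Illumina bead arrays, per the labels' protocols. The deposited table of intensity values holds bead summary intensities per probe on a linear scale, not normalized, with the lowest value of every array well above 0. Beside each intensity the deposited table gives a detection p-value for each probe and array, per the file headers. A second deposited table holds log2 values that the authors had quantile normalized, since all columns share the median of 7.046 and each lies within 0.148 of the log2 intensities after quantile normalization. Its scale is log2 and uncentred, and its direction does not apply to single-channel values. GenomeStudio 2011.1 and R 3.0.2 are named per the submitters' processing notes. No genome build applies.

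Samples were grouped by their titles into HF, HFGSC and GSC, with 2 arrays each, and all 6 value columns were matched to samples, leaving 0 unused. Array mean intensities lay between 911 and 1149. Probes were named from the platform annotation. Of 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none. For 34807 probes the Entrez identifier matched the RefSeq table of assembly GRCm38.p6, which was used for names and changed 0 symbols.

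Intensities were processed with neqc of limma 3.58.1 in R 4.3.3: background correction inferred from detection p-values, an offset of 16, quantile normalization and log2. Probes with a detection p under 0.05 on both arrays of at least 1 group were kept, and the probe with the highest mean stood for its gene, leaving 10913 genes. Linear models were fitted to all 6 arrays, which share 1 estimate of the spread with 3 residual degrees of freedom, and moderated with a mean-variance trend. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Where a gene's probe was not detected on either array of the dimmer group, the fold is a lower bound: the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the lowest detected signal and the probe's own signal. Other folds come from differences of group means. The labels tie replicate numbers to no animal or batch. Differences between replicates 1 and 2 correlated across genes at 0.436 between HF and HFGSC, 0.757 between HF and GSC and 0.58 between HFGSC and GSC, so the numbers were taken, from the data alone, to pair the arrays. Pairing remains an assumption. Each group gives 1 difference, whose sign rests on the numbering, so variation common to the groups could correlate this way without pairing. The fit planned without the number stayed the reported one. Values with the number as a block are given where a list call ended, or a printed count moved by more than 1.5-fold or to or from 0. Smaller moves are mostly not printed. In HFGSC against HF, for example, higher Wnt pathway genes went from 7 to 10 and higher germ cell core genes from 20 to 23. The pairing was settled after the counts of both fits had been seen. Array distances are root mean square log2 differences over the tested genes.

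Before the data were examined, 31 gene lists were fixed, along with the comparisons, tests and alternatives. Lists with 5 or more tested members, except the sex-linked check, were tested with camera at a preset correlation of 0.01 and adjusted over the lists. Some lists share members, so their results are not separate lines of evidence. Thy1 is in the fibroblast list and among spermatogonial surface markers, Sall4 among stem cell regulators and pluripotency genes. Dppa4 is in the pluripotency and primordial germ cell lists, and Kit in the primordial germ cell and melanocyte lists. No list passed in any of the 3 comparisons with an estimated correlation, which rests on 3 residual degrees of freedom. Named genes followed a rule fixed in advance: per comparison, the 10 largest increases and 10 largest decreases among genes that passed, with every array of one group on one side of every array of the other, leaving out unnamed loci, and from each list up to 4 genes with the smallest adjusted p. Genes named outside that rule were chosen after their values were seen. They are the keratins and mesenchymal genes of the HF description, Hlx in the overlap and list members that moved against their list. Untested members of the pluripotency, meiosis, leukocyte and melanocyte lists and genes whose probes were compared are the others. The median, mean and camera direction of a list differed in sign only in lists that did not pass or were not tested: basal keratinocyte in each comparison; sebocyte, BMP and TGF-beta, and cholesterol in HFGSC vs HF; adipocyte in GSC vs HF; and spermatogonial regulators, primordial germ cell and Sertoli cell in HFGSC vs GSC.

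The gene test was tested on simulated data, 10913 genes with 200 changed by known folds, in 20 draws. For HFGSC against HF it recovered 4.8% of genes changed 2-fold, 47.4% of 4-fold, 86.1% of 8-fold and 97.7% of 16-fold changes. For GSC against HF the shares were 5.9%, 45.1%, 84.2% and 98.3%. For HFGSC against GSC they were 5.7%, 40.6%, 84.6% and 97.7%, so 2-fold differences between these groups were mostly out of reach. Unchanged genes made up 5.94% of the simulated calls for HFGSC against HF, 8.36% for GSC against HF and 6.04% for HFGSC against GSC. Each of these shares lay above the share that the adjusted p threshold is meant to allow. Alternatives covered background correction, normalization, the deposited log2 values, the detection filter, probe averaging, the replicate number as a block, the arrays in the fit, the trend, stricter thresholds, and leaving out each array. Where an array was left out, the lone array of its group is assumed to vary like the others.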

Results

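Gene expression was measured on 6 bead arrays from mice of the OG2 strain, which carries a green fluorescent reporter under regulatory sequences of the pluripotency gene Pou5f1. The samples formed 3 groups of 2 arrays. HF arrays held RNA of hair follicle cells from dorsal skin of 2-month-old mice. HFGSC arrays held RNA of cells described as germline stem cells derived from hair follicles, from 4-month-old mice. GSC arrays held RNA of germline stem cells from the testis of 3-month-old mice. The study set HFGSC and GSC against HF cells, and the arrays also allow HFGSC to be set against GSC. Of the 45281 probes, 16593 and 16094 were detected on the HF arrays, 19552 and 18907 on the HFGSC arrays, and 19476 and 18772 on the GSC arrays. After filtering, 10913 genes were tested. With 2 arrays per group, the number of arrays limits the precision of every value, and no exact test of 2 against 2 arrays can give a two-sided p under 0.333. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

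Cell type markers on the HF arrays were mixed, and those named here were chosen after their values were seen. On both HF arrays 12 of 27 fibroblast and matrix genes were detected, 9 of 18 bulge stem cell genes, 8 of 15 neural crest genes and 4 of 15 basal keratinocyte genes. Of all genes on the array 44.1% were detected there. The fibroblast and bulge shares lay near that value, so these counts alone do not mark a cell type. Vim, an intermediate filament gene of mesenchymal cells, had a mean log2 intensity of 14.38 ± 0.02 (SD, n = 2), and the matrix gene Sparc had 14.20 ± 0.27 (SD, n = 2). Col1a1, a fibrillar collagen, had 12.85 ± 0.10 (SD, n = 2). Krt5 and Krt14, keratins of basal keratinocytes, and Krt15, a marker of the follicle bulge, were not detected on any of the 6 arrays, nor was Trp63, a regulator of stratified epithelium. Krt1, a keratin of differentiating epidermis, and the pan-leukocyte gene Ptprc were likewise not detected on any array. Other fibroblast genes were at background in HF, among them Dcn at 5.08 ± 0.20 (SD, n = 2).

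Sex-linked genes were read on every array. One Eif2s3y probe, a Y-linked gene, was not detected on the HF arrays, at 4.92 on each, and was detected on all other arrays, at 10.77 and 7.80 on the HFGSC arrays and 11.04 and 7.80 on the GSC arrays. A second Eif2s3y probe did not separate the groups, at 5.77 and 6.24 in HF, 5.46 and 5.66 in HFGSC, and 5.63 and 6.25 in GSC, and was detected on 1 array. A Kdm5d probe read 6.96 and 5.10 in HF, 6.59 and 5.43 in HFGSC, and 7.31 and 5.07 in GSC, and was detected on 3 arrays, while a second was detected on 0. A Uty probe was detected on all 6 arrays, at 7.19 and 7.11 in HF, 6.67 and 6.11 in HFGSC, and 6.83 and 6.30 in GSC, and 3 others were not detected on any array. None of the 4 Xist probes was detected on any array. The arrays leave open which cells and which sex the HF samples held, and the groups differ in age, so differences against HF include any effect of these.

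HFGSC cells of 4-month-old mice were compared with HF cells of 2-month-old mice. Dlk1, an imprinted gene, had a mean log2 intensity of 15.71 ± 0.25 (SD, n = 2) in HFGSC and 5.17 ± 0.15 (SD, n = 2) in HF, at least 616-fold higher (limma adjusted p = 1.57e-05). Ret, the receptor component for the growth factor GDNF, was at least 264-fold higher (adjusted p = 4.08e-05), and Tex19.1, a germ cell gene, at least 229-fold higher (adjusted p = 4.08e-05). Fah, the last enzyme of tyrosine breakdown, was at least 136-fold lower (adjusted p = 0.000233).

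In all, 2896 of the 10913 genes passed an adjusted p of 0.05 in limma, 1873 higher and 1023 lower in HFGSC. Among the genes with the largest increases, Large2 was at least 292-fold, Gpat2 196-fold, Igf2 184-fold, Mageb4 171-fold, Dcn 171-fold, Col6a1 162-fold and Egr4 155-fold higher, each as a lower bound. Among the largest decreases, St3gal6 was at least 98.8-fold, Tinagl1 86.5-fold, Pcdh17 57.8-fold, Mlkl 55.4-fold, Il24 55.3-fold, Adh7 42.8-fold, Car13 42.6-fold and Tfap2b 36.5-fold lower. Htra1, a secreted protease gene detected on 1 of the 2 HFGSC arrays, was 82.1-fold lower (log2 difference -6.36, SE 0.58). The adjusted p of these genes lay between 4.08e-05 and 0.000654. The count was 1505 without HF replicate 1 (993 higher, 512 lower) and 1525 without HF replicate 2 (1086 higher, 439 lower), and without HFGSC replicate 1 the lower genes were 517 and the higher 1455. With the replicate number as a block it was 5122, 2876 higher and 2246 lower.

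Of 21 tested regulators of spermatogonial stem cells, 19 rose, none fell and 2 did not pass; 19 also rose adjusted over the list alone. Besides Ret, Sall4 was at least 112-fold and Egr2 at least 94.7-fold higher, and Uchl1 was 94.3-fold higher. The list passed the camera test with its preset correlation (adjusted p = 1.17e-11) and not with an estimated correlation (adjusted p = 0.284). In the germ cell core list 20 of 27 genes rose and 7 did not pass, or 22 adjusted over the list alone (camera adjusted p = 1.61e-12; adjusted p = 0.445 with an estimated correlation). Sohlh1, a transcription factor of spermatogonia, was at least 138-fold higher, and Piwil2, of the piRNA pathway, at least 99.7-fold higher. In the pluripotency list 12 of 16 genes rose and 1 fell, or 13 and 1 adjusted over the list alone (camera adjusted p = 4.57e-06; adjusted p = 0.445 with an estimated correlation). Tcl1 was at least 66.3-fold and Esrrb at least 22.5-fold higher, and the gene that fell was Klf5 (log2 difference -2.17, SE 0.54). The array held 23 genes of this list. Those not tested, Nanog, Sox2, Dppa2, Tdgf1, Fgf4, Nr0b1 and L1td1, were not detected on any array of any group.

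Of 12 tested meiosis genes 8 rose, also adjusted over the list alone (camera adjusted p = 0.00347, and adjusted p = 0.445 with an estimated correlation). Rec8, a meiotic cohesin, was at least 8.84-fold higher and Stag3 15.3-fold higher. The array held 23 meiosis genes. Among those not tested, Stra8, Sycp3, Dmc1 and Hormad1 were not detected on any array of any group, and Sycp1 and Sycp2 were each detected on 2 arrays. Of 10 genes of primordial germ cell specification 5 rose, or 6 adjusted over the list alone (camera adjusted p = 0.0163; adjusted p = 0.538 with an estimated correlation), with Dppa4 at least 72.7-fold and Kit at least 8.19-fold higher. That call was lost without HFGSC replicate 2 (adjusted p = 0.0675). Of 16 imprinted genes 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.0012; adjusted p = 0.284 with an estimated correlation). Cdkn1c was at least 128-fold and Mest at least 86.1-fold higher, and Peg10 fell (log2 difference -2.23, SE 0.50). Of 14 Wnt pathway genes 7 rose, or 8 adjusted over the list alone (camera adjusted p = 0.0012; adjusted p = 0.284 with an estimated correlation), with Fzd10 at least 47.1-fold and Axin2 at least 5.32-fold higher.

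Fibroblast and matrix genes rose in HFGSC in 13 of 24 cases and fell in 1, or 14 and 1 adjusted over the list alone (camera adjusted p = 0.00144; adjusted p = 0.798 with an estimated correlation), and 14 and 2 with the replicate block. Thy1 was at least 78.0-fold and Lox at least 30.4-fold higher, whereas Vim fell (log2 difference -2.96, SE 0.66). Without HFGSC replicate 2 the list did not pass (adjusted p = 0.12). Proliferation genes fell in 7 of 25 cases and rose in none, or 8 and none adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.445 with an estimated correlation); with the replicate block 11 fell and 4 rose. Rrm2 was 9.83-fold, Birc5 3.82-fold and Plk1 3.52-fold lower. Without HF replicate 1 this list did not pass (adjusted p = 0.131). With genes at their lower bounds, the list medians were 3.38 for stem cell regulators, 3.86 for germ cell core, 3.23 for pluripotency, 1.25 for meiosis and 0.93 for fibroblast genes, against 4.59, 4.83, 3.75, 2.32 and 1.77 as fitted.

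**Figure D1:**
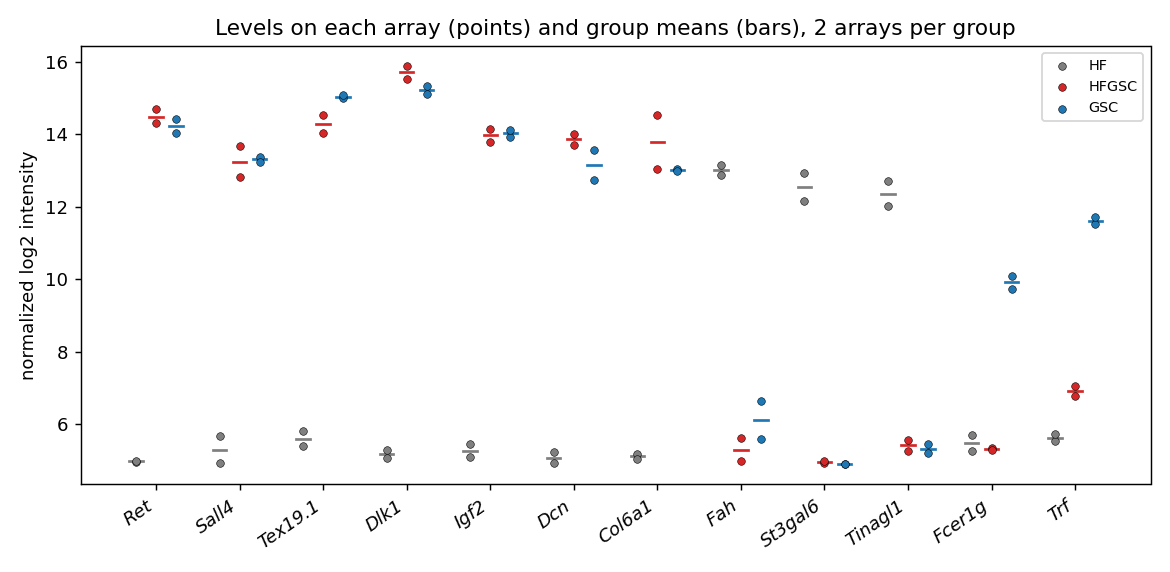
Normalized log2 intensity of 12 genes on each array. Points are the 2 arrays of a group and bars are group means. Dlk1 has a mean of 15.71 in HFGSC, 15.22 in GSC and 5.17 in HF, while Fah has 5.30, 6.11 and 13.02.

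GSC cells were compared with the same HF arrays. Dlk1 was at least 438-fold (limma adjusted p = 2.25e-05), Tex19.1 at least 387-fold (adjusted p = 3.33e-05) and Mageb4 at least 286-fold higher in GSC (adjusted p = 7.99e-05). Dazl, a germ cell RNA-binding protein gene, was at least 208-fold higher (adjusted p = 0.000187). St3gal6 was at least 97.7-fold lower (adjusted p = 0.000123).

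In this comparison 3501 genes passed in limma, 2127 higher and 1374 lower in GSC. The other largest increases were those of Large2 at 273-fold, Gpat2 at 247-fold, Cdkn1c at 231-fold, Ret at 220-fold, Taf7l at 196-fold and Xlr4a at 157-fold, each as a lower bound. Tinagl1 was at least 85.6-fold, Csrp1 at least 61.9-fold, Pcdh17 at least 57.2-fold, Il24 at least 54.8-fold and Car13 at least 42.2-fold lower. Fah was 120-fold, Htra1 84.7-fold, Rnpep 71.3-fold and Eng, an endothelial receptor gene, 70.6-fold lower, where the probes of Fah, Rnpep and Eng were detected on 1 of the 2 GSC arrays. The count was 1819 without HF replicate 1, 2086 without HF replicate 2, 2263 without GSC replicate 1 and 1853 without GSC replicate 2, of which 695, 716, 611 and 605 were lower. With the replicate number as a block it was 5669, 3173 higher and 2496 lower.

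In GSC 22 of 27 germ cell core genes rose, or 24 adjusted over the list alone (camera adjusted p = 1.14e-12; adjusted p = 0.513 with an estimated correlation), among them Sohlh1 at least 266-fold. Of 21 stem cell regulators 18 rose, also adjusted over the list alone (camera adjusted p = 2.42e-09; adjusted p = 0.38 with an estimated correlation), with Sall4 at least 117-fold and Bcl6b at least 51.4-fold higher. Of 16 pluripotency genes 14 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 4.72e-06; adjusted p = 0.513 with an estimated correlation), with Tcl1 at least 88.0-fold and Dppa5a 52.5-fold higher and Klf5 (-1.80) and Tbx3 (-1.92) lower on the log2 scale. Imprinted genes rose in 9 of 16 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 0.00168; adjusted p = 0.38 with an estimated correlation), with Igf2 at least 191-fold and Ndn 40.4-fold higher and Peg10 at -1.92 on the log2 scale. Wnt pathway genes rose in 9 of 14 cases, also adjusted over the list alone (camera adjusted p = 0.00168; adjusted p = 0.38 with an estimated correlation), with Fzd10 at least 23.7-fold and Nkd1 at least 6.58-fold higher. With genes at their lower bounds, the list medians were 4.36 for germ cell core, 3.70 for stem cell regulators, 3.07 for pluripotency, 0.55 for imprinted genes and 1.62 for the Wnt pathway, against 5.48, 3.73, 4.17, 1.22 and 1.84 as fitted.

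Of 12 meiosis genes 7 rose in GSC, also adjusted over the list alone (camera adjusted p = 0.00216; adjusted p = 0.513 with an estimated correlation), with Hormad2 at least 8.16-fold higher. Genes of DNA methylation and chromatin rose in 6 of 15 cases, also adjusted over the list alone (camera adjusted p = 0.0177; adjusted p = 0.748 with an estimated correlation). Dnmt3b, a de novo DNA methyltransferase, was higher by a log2 difference of 4.26 (SE 0.40) and its cofactor Dnmt3l at least 10.3-fold higher. That list did not pass without HF replicate 2 (adjusted p = 0.103), without GSC replicate 1 (adjusted p = 0.0766) or with median scaling (adjusted p = 0.051). Primordial germ cell genes rose in 7 of 10 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.039; adjusted p = 0.731 with an estimated correlation), and did not pass without HFGSC replicate 1 (adjusted p = 0.0765) or HFGSC replicate 2 (adjusted p = 0.0773), or with the replicate block (adjusted p = 0.0706). Pou5f1 was 17.1-fold and Dppa3 at least 3.83-fold higher, and the genes that fell were Ifitm1 (log2 difference -2.08) and Ifitm3 (log2 difference -2.07), which are also interferon-induced.

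Leukocyte genes rose in GSC in 4 of 6 tested cases and fell in 1, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0489; adjusted p = 0.757 with an estimated correlation). The array held 21 genes of this list, of which 6 were detected on both GSC arrays and 2 on both HF arrays. Among those not tested, Ptprc, Cd74, Itgam and Tyrobp were not detected on any array of any group. Fcer1g was at least 11.1-fold and Coro1a 17.9-fold higher, and Cd14 was 11.8-fold lower. The list did not pass without HF replicate 2 (adjusted p = 0.0531), HFGSC replicate 1 (adjusted p = 0.167), HFGSC replicate 2 (adjusted p = 0.0567) or GSC replicate 2 (adjusted p = 0.0731), nor with median scaling (adjusted p = 0.051), without the trend (adjusted p = 0.0627) or with the replicate block (adjusted p = 0.111). Glycolysis genes fell in 4 of 16 cases and rose in 2, also adjusted over the list alone (camera adjusted p = 0.0404; adjusted p = 0.809 with an estimated correlation). Pgk1 was 8.70-fold and Hk1 6.18-fold lower, whereas Aldoc was at least 65.3-fold higher and Pdk1 rose by a log2 difference of 1.15. That list did not pass without HF replicate 2 (adjusted p = 0.103), GSC replicate 1 (adjusted p = 0.0717) or the trend (adjusted p = 0.0714), and with the replicate block 8 of its genes fell and 2 rose. The fibroblast list rose in 9 of 24 cases and fell in 3, or 10 and 3 adjusted over the list alone and 11 and 6 with the replicate block, and did not pass camera (adjusted p = 0.17). Of 25 proliferation genes 3 rose and 4 fell in GSC, also adjusted over the list alone, and 6 and 10 did with the replicate block; the list did not pass camera (adjusted p = 0.407).

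Several lists of other skin and testis cell types did not pass camera in either comparison with HF. Basal keratinocyte genes rose in 3 of 7 cases and fell in 3 in HFGSC (adjusted p = 0.921) and did so in GSC as well (adjusted p = 0.887), with Col17a1 at least 13.2-fold higher and Lamb3 at least 8.26-fold lower in HFGSC. Bulge genes rose in 6 of 13 cases and fell in 2 in HFGSC (adjusted p = 0.222), and rose in 3 and fell in 2 in GSC (adjusted p = 0.639), or 6 and 3 with the replicate block. Melanocyte genes rose in 3 of 6 tested cases and fell in 1 in HFGSC (adjusted p = 0.228), and rose in 5 and fell in 1 in GSC (adjusted p = 0.138), the lower one being Gpnmb. The array held 14 melanocyte genes, and among those not tested, Tyr, Tyrp1 and Mitf were not detected on any array. Sertoli cell genes rose in 4 of 8 cases and fell in 1 in HFGSC (adjusted p = 0.218) and rose in 3 in GSC (adjusted p = 0.303), where Trf was at least 36.1-fold higher. Neural crest genes rose in 3 of 10 cases and fell in 3, or 5 with the replicate block, in HFGSC (adjusted p = 0.487), and rose in 2 and fell in 4 in GSC (adjusted p = 0.169).

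The remaining lists did not pass either, given here as adjusted p in HFGSC and then in GSC against HF. Of 9 tested spermatid genes, from 24 on the array, 5 rose and 1 fell in HFGSC, and 4 rose and 0 fell in GSC (0.219 and 0.102). Of 7 hair shaft genes 3 rose and 2 fell in HFGSC, and 4 rose and 2 fell in GSC (0.714 and 0.639). Of 6 muscle genes 3 rose and 0 fell in HFGSC, and 3 rose and 1 fell in GSC (0.38 and 0.555). Of 13 interferon response genes 1 rose and 3 fell in HFGSC, and 1 rose and 4 fell in GSC (0.236 and 0.12). The replicate block moved the counts of lower genes to 1 for muscle in HFGSC, 1 for spermatid in GSC and 7 for interferon response in GSC, and the higher interferon genes in HFGSC to 2. The values were 0.948 and 0.858 for surface markers shared with epithelia, 0.556 and 0.864 for epidermal differentiation, 0.905 and 0.542 for sebocyte, and 0.714 and 0.858 for endothelial genes. They were 0.905 and 0.582 for BMP and TGF-beta signalling, 0.905 and 0.577 for cholesterol biosynthesis, and 0.899 and 0.639 for immediate early and heat shock genes. In HFGSC the leukocyte list gave 0.332, the glycolysis list 0.218 and the DNA methylation list 0.18. Leydig cell and adipocyte lists had too few tested members, 2 and 3. Between HFGSC and GSC the smallest adjusted p among lists that did not pass was 0.0981, for neural crest.

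**Figure D2:**
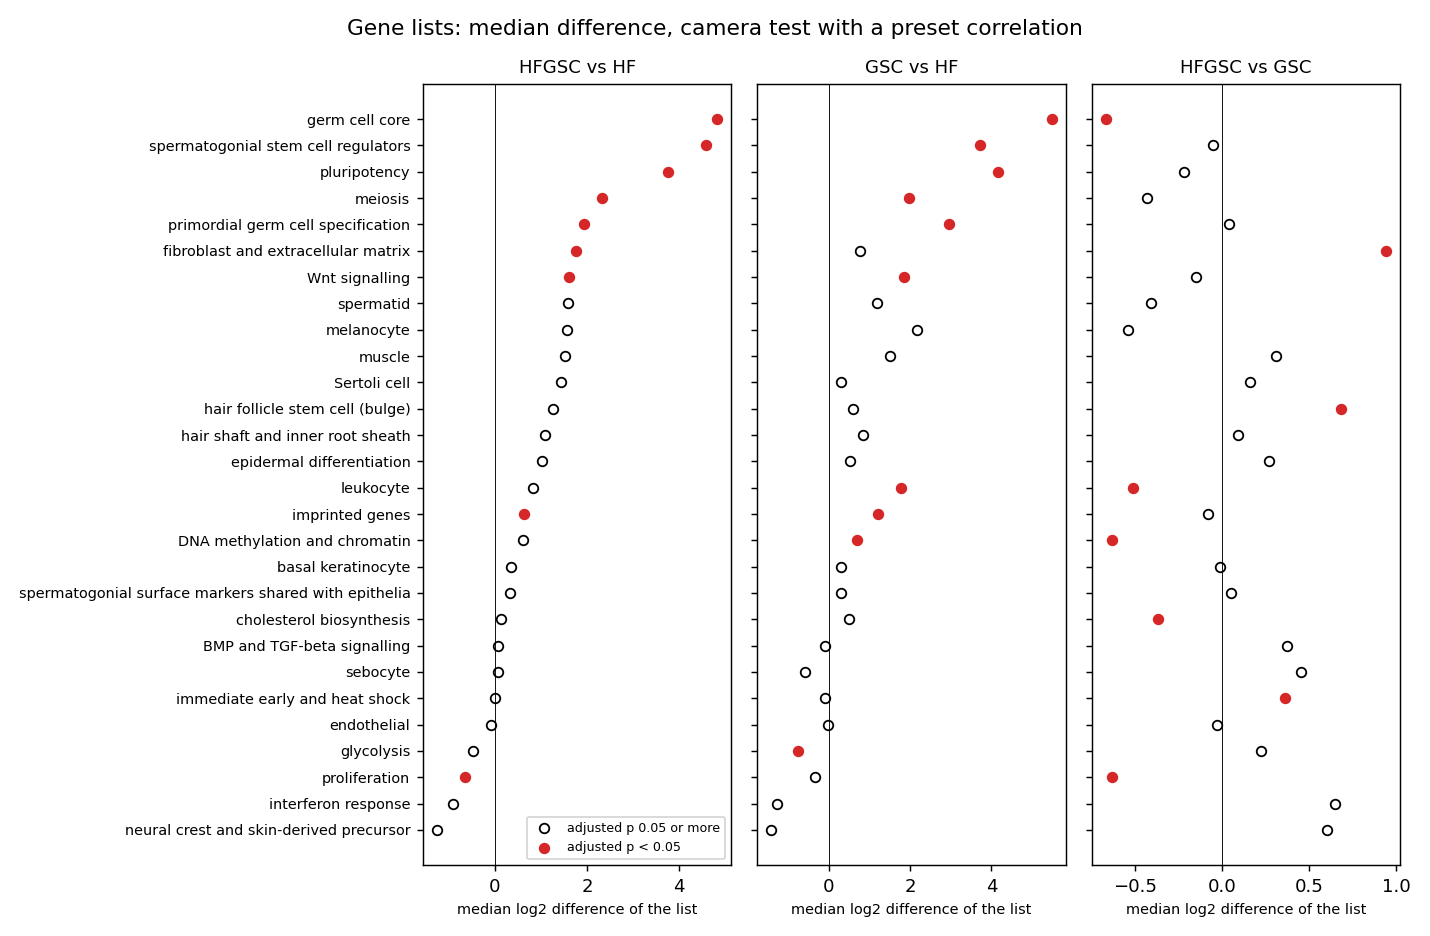
Median log2 difference of each tested gene list in the 3 comparisons. Filled points are lists with a camera adjusted p under 0.05 at the preset correlation, 9, 10 and 8 in the order of the panels, whose horizontal scales differ.

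HFGSC and GSC calls against HF overlapped widely. Of the called genes 1565 were higher in both and 860 lower in both, where independent lists of these sizes would share 365 and 129. Simulated unchanged groups against shared HF arrays gave at most 1 such gene in 100 draws. The simulated genes were independent and changed in neither group, so almost none could be called. That count therefore cannot tell how many calls would be shared by groups that do differ from HF. The fold changes correlated across genes at 0.93, against 0.50 in the simulation, and their covariance was 2.95 against 0.21. Genes are not independent replicates, and 2 HF arrays cannot be split into sets of 2, so part of the excess may come from the shared controls. The 2425 shared genes became 1190 without HF replicate 1, 1266 without HF replicate 2 and 1511 without GSC replicate 2, and the 860 lower ones 444, 388 and 478. Without HFGSC replicate 1 and without GSC replicate 1 the lower ones were 456 and 486. With the replicate number as a block 4247 were shared, 2435 higher and 1812 lower. Hlx, a homeobox gene chosen here after its values were seen, was the 1 gene called in opposite directions, with mean log2 intensities of 10.07 in HFGSC, 8.05 in HF and 5.78 in GSC.

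**Figure D3:**
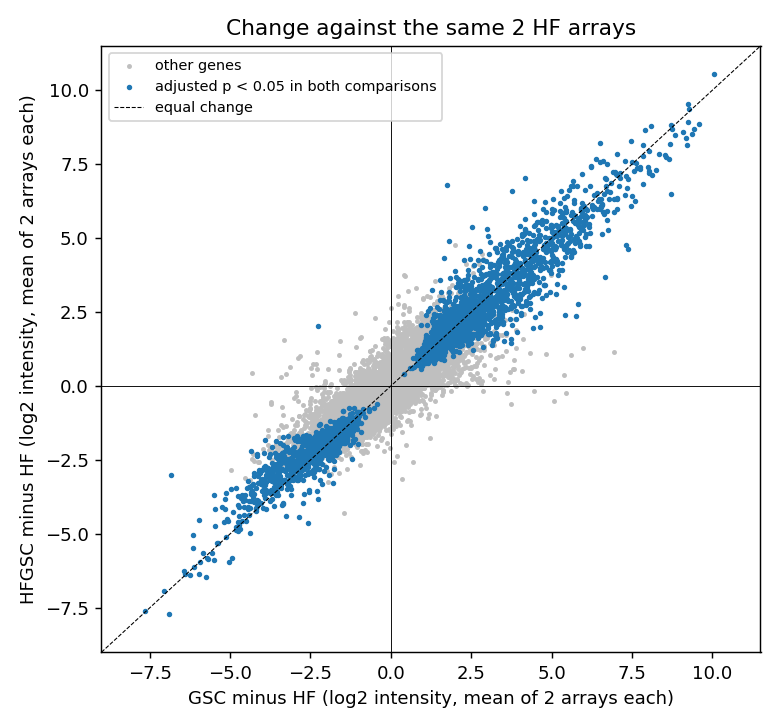
Change of each gene in HFGSC (vertical) and in GSC (horizontal) against the same HF arrays, as log2 differences of means of 2 arrays. Blue points are genes called in both comparisons, and the dashed line marks equal change. Of these genes 1565 lie above 0 on both axes, 860 lie below, and 1, Hlx, has opposite signs.

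HFGSC arrays lay nearer to GSC than to HF. The root mean square log2 difference over the tested genes averaged 0.929 ± 0.232 (SD over 4 array pairs) between HFGSC and GSC and 1.846 ± 0.125 (SD over 4 array pairs) between HFGSC and HF. Within groups it was 0.737 in HF, 0.986 in HFGSC and 0.861 in GSC. Each within-group distance joins replicates 1 and 2, whose differences correlated between groups. Pairs of HFGSC and GSC arrays with different replicate numbers lay at 0.925 and 1.201, and those with the same number at 0.635 and 0.954. The distances therefore leave open whether HFGSC differed from GSC by more than its own replicates differed. The smallest distance was between HFGSC replicate 1 and GSC replicate 1, at 0.635, and HFGSC replicate 2 lay 1.201 from GSC replicate 1.

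Fewer genes passed between HFGSC and GSC than in either comparison with HF. Trf, the iron carrier transferrin, was 26.3-fold lower in HFGSC (limma adjusted p = 0.0145), and Fcer1g, an immune receptor chain, at least 15.9-fold lower (adjusted p = 0.0119). Dppa3, a marker of primordial germ cells, was 6.28-fold lower (adjusted p = 0.0322) and detected on 1 of the 2 HFGSC arrays. Pou5f1 was 5.73-fold lower in HFGSC (log2 difference -2.52, SE 0.51) and did not pass (limma adjusted p = 0.126). Of 16 pluripotency genes 0 were lower and of 10 primordial germ cell genes 1 was, or 1 and 2 with the replicate block. Hlx, detected on 1 of the 2 GSC arrays, was 19.6-fold higher (adjusted p = 0.0305). Casp9, an initiator caspase, was 33.4-fold higher by its brightest probe (adjusted p = 0.0119), but a second detected probe went the other way, as it did for Trappc12, and the second probes of Rps3 and Cpsf4l moved by less than 0.5 of the called log2 difference.

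Of 10913 genes 48 passed in limma, 19 higher and 29 lower in HFGSC, and 803 had an unadjusted p under 0.05. Other large increases were Mettl14 at 27.7-fold, Cops8 at 14.5-fold, Gpn2 at 13.8-fold, St6gal1 at 9.17-fold, Tmprss2 at 8.55-fold and Rps3 at 7.28-fold, with Csrp1 at least 7.61-fold and Bcl11b at least 6.72-fold higher. Other large decreases were Pkd2l1 at 55.0-fold, Rab25 at 32.8-fold, Dpep3 at 23.5-fold, Rapsn at 20.3-fold and Magea6 at 13.5-fold, with Cpsf4l at least 32.0-fold, Rbm45 at least 29.9-fold and Svs5 at least 9.39-fold lower. In the dimmer group the probes of Mettl14, Pkd2l1, Rab25 and Magea6 were detected on 1 of 2 arrays. The count fell to 0 without HFGSC replicate 2, where limma gave 560 genes with an unadjusted p under 0.05. It was 23 without HF replicate 1, 21 without HF replicate 2, 18 without GSC replicate 1 and 10 without GSC replicate 2, and 5 with only these groups fitted and 13 without the trend. With the replicate number as a block it was 174, 86 higher and 88 lower, with 2001 at an unadjusted p under 0.05. Leaving out an HFGSC or GSC array sets 1 replicate number against both without a block, so any effect of the number enters those counts and directions. The balance of directions turned with single arrays: without HFGSC replicate 1 it was 51 higher and 13 lower, 64 in all, against 1 higher and 17 lower without GSC replicate 1 and 1 and 9 without GSC replicate 2. None of the 20 genes with the largest changes kept its call with each array left out in turn.

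No spermatogonial regulator passed on its own, whether over all genes or, except for 1 higher gene, adjusted over the list alone, and camera gave an adjusted p of 0.24. All 24 fibroblast and matrix genes had higher means in HFGSC, none passing alone or adjusted over the list alone, and the list passed camera (adjusted p = 3.32e-07; adjusted p = 0.724 with an estimated correlation). Its median difference was 0.94, with Timp2 at 1.28 and Col3a1 at 1.84. Without HFGSC replicate 2 the list did not pass (adjusted p = 0.512). The proliferation list had a median of -0.63 (camera adjusted p = 0.000158; adjusted p = 0.724 with an estimated correlation), with Cdc20 at -1.01, and did not pass without GSC replicate 1 (adjusted p = 0.0763). The DNA methylation list had a median of -0.63 (camera adjusted p = 0.00793) and germ cell core one of -0.67 (camera adjusted p = 0.0111), each with an adjusted p of 0.724 with an estimated correlation. Without HFGSC replicate 2 they gave 0.512 and 0.953, the direction of germ cell core turning to higher in HFGSC, and without GSC replicate 1 they gave 0.226 and 0.984, as adjusted p.

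Lists for leukocyte, bulge, cholesterol synthesis, and immediate early and heat shock genes passed camera narrowly between HFGSC and GSC (adjusted p = 0.0454 for each; adjusted p = 0.724 for each with an estimated correlation). Their medians were -0.51, 0.68, -0.37 and 0.36. Of their members Fcer1g alone passed over all genes; adjusted over the list alone 2 leukocyte genes were lower and 2 bulge genes higher, and with the replicate block 1 bulge gene was higher. The bulge median was 0.05 with genes at their bounds. Without HFGSC replicate 2 the bulge list had an adjusted p of 0.299, the cholesterol list 0.402 and the immediate early list 0.512, and without HFGSC replicate 1 the leukocyte list had 0.634. Without GSC replicate 1 the bulge, cholesterol and immediate early lists had 0.286, 0.226 and 0.0561, and without GSC replicate 2 the leukocyte, cholesterol and immediate early lists had 0.234, 0.167 and 0.231. The cholesterol list also did not pass without HF replicate 2 (adjusted p = 0.053). With the replicate block the leukocyte and bulge lists did not pass, at 0.139 and 0.0524. With normexp none of these lists passed, at 0.0563 for leukocyte and 0.0501 for each of the others. With median scaling the leukocyte list had 0.0565, the cholesterol list 0.0643 and the immediate early list 0.126. With probes averaged the bulge list had 0.0893 and the cholesterol list 0.159, and without the trend the bulge, cholesterol and immediate early lists had 0.0748 each.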

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

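The unnamed probes below are given because they lie outside the comparisons by gene, and Hlx because its changes against HF differ between groups. Among 2947 detected probes without a single gene symbol, 291 were higher in HFGSC than in HF and 361 were higher in GSC than in HF in limma, and 261 and 318 were lower. Their genes are unnamed here. With each array left out, a check chosen after the result was seen, the higher counts ran from 101 (without HF replicate 1, and without HF replicate 2) to 313, with 178 without HFGSC replicate 1. In GSC they ran from 127 (without GSC replicate 2) to 393, with 137 and 155 without HF replicates 1 and 2 and 234 without GSC replicate 1. With the replicate block, 496 and 614 were higher and 570 and 641 lower. Lower counts fell as far as 91 without HFGSC replicate 1 and 62 without GSC replicate 2. The share of these probes called was 18.7% and 23.0%, against 26.5% and 32.1% of named genes. Each unnamed probe was counted, in a fit of its own set, whereas a named gene stood by its brightest probe, so the shares are not directly comparable. Hlx rose against HF in HFGSC (log2 difference 2.02, adjusted p = 0.0356) and fell in GSC (log2 difference -2.27, adjusted p = 0.0204). The test of the difference itself, HFGSC minus GSC, gave 4.29 (adjusted p = 0.0305), with 1 detected probe behind the gene.

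All tests in this paragraph were chosen after the results were seen. The fibroblast and matrix list was higher in HFGSC than in GSC in 100% of its 24 members. Cells of the HF population as the source are argued against by the 11 members not detected on either HF array, whose median difference was 0.80 with all 11 positive. The array HFGSC replicate 2 alone may account for most of the shift: HFGSC replicate 1 by itself had a median difference of 0.18 from the GSC mean, with 15 of 24 members higher, while HFGSC replicate 2 had 1.83 with 24 of 24. A larger share of other fibroblast-type cells on that array is a candidate explanation that the 100% figure leaves open. A difference between the groups in origin or age stays open and untested.

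The comparison with HFGSC vs HF calls below was fixed before its result was seen, and the other tests after. Of the 48 genes called between HFGSC and GSC, 9 had a second detected probe. For 5 of them (Ahsg, Col18a1, Pamr1, Rab25, Rapsn) it moved the same way by at least 0.5 of the called log2 difference, which argues against a sequence variant or transcript form under 1 probe. For the other 4 (Casp9, Cpsf4l, Rps3, Trappc12) it did not, so such a variant or form may underlie the call. Probe disagreement was 44.4% here and 25.5% among HFGSC vs HF calls (Fisher's exact test, two-sided p = 0.246), and 9 genes are too few to say whether the rates differ. The 39 genes with 1 detected probe could not be examined.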

How the results depend on the processing

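The tests of the replicate pattern were chosen after the result was seen. The 20 largest changes of HFGSC vs HF and of GSC vs HF kept direction and call in every alternative run, but of all called genes chosen by the naming rule 78 of 115 and 82 of 119 did. Kept direction with an array left out was largely fixed by the naming rule, which required every array of one group on one side of the other. Between HFGSC and GSC 32.3% of all tested genes were separated in this way, against 33.3% if the arrays of both groups were interchangeable. A replicate number effect common to the groups would make the latter share smaller, so these values leave open whether separation exceeded chance. Of the 20 largest changes of HFGSC vs GSC 19 kept direction in every run, Casp9 being the exception, and none kept its call in every run. Without HFGSC replicate 2, where limma called 0 genes with 560 at an unadjusted p under 0.05, their median size was 4.32 against 4.31 with all arrays. At an adjusted p of 0.01 limma called 1341, 1715 and 0 genes in HFGSC vs HF, GSC vs HF and HFGSC vs GSC, the last with 803 at an unadjusted p under 0.05. HFGSC vs GSC gave 5 genes with only those groups fitted and 13 without the trend. Fits with an array left out had no block and set a single replicate number against both, so they cannot part 1 array from the number. With each array left out, counts ran from 1505 to 2829, 1819 to 3855 and 0 to 64, and shared genes from 1190 to 2500; one array fewer also leaves fewer residual degrees of freedom. No list passed with an estimated correlation (0, 0 and 0, with 3, 3 and 1 at an unadjusted p under 0.05). Lists passing HFGSC vs GSC were 4 with normexp, 5 with median scaling, 5 without the trend and 3 to 11 with arrays left out; those against HF were 8 to 10 and 7 to 11. Without HFGSC replicate 2 the germ cell core list turned to the other direction between HFGSC and GSC (adjusted p = 0.953; 9.12e-06 to 0.984 over its alternatives), and the cause was not tested. Casp9 HFGSC vs GSC read -1.30 without HFGSC replicate 1, where its other probe was the brighter, and up to 5.20 elsewhere. Median scaling moved the median GSC vs HF difference of all genes from 0.07 to 0.16. Signal over background limits dim genes, whose folds are bounds.

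Distances HF to HFGSC, HF to GSC and within HFGSC were 1.511, 1.592 and 0.842 with normexp, 1.411, 1.487 and 0.805 without background correction, 1.391, 1.467 and 0.800 on the deposited log2 values, and 1.424, 1.493 and 0.781 without the filter. Within HF they were 0.580 without background correction and 0.573 on deposited values, and within GSC 0.692, 0.687 and, without the filter, 0.688. HF to GSC was 2.021 at the stricter filter and 1.843 with probe means. The ratio of the HF to the GSC distance of HFGSC stayed between 1.91 and 2.02, and between 1.61 and 2.46 with arrays left out.

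With the replicate block 5122, 5669 and 174 genes were called and 4247 shared. It ended 4 list calls, given with those lists, and no other; of the genes chosen by the naming rule 6, 4 and 3 gained a call and 0 lost one. The lowest correlation of replicate differences between groups was 0.44, so a batch shared by number may exist, but a single difference per group cannot establish it. Normalization is argued against as the cause by 0.50 on unprocessed log2 intensities. The median replicate difference of the fibroblast list was -0.03 in HF, -1.69 in HFGSC and -0.14 in GSC. The HF value cannot decide on a fibroblast share, since 11 of the 24 members were not detected on either HF array. In GSC, where 22 list genes were detected on both arrays, -0.14 argues against such a share as a cause common to the 3 groups.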

Other observations

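The families below were chosen after the values were seen, as was the check of their counts under other scalings. X-linked cancer-testis genes of the Magea family rose in GSC against HF in 6 of 6 tested cases in limma, and in HFGSC in 4 of 6. The counts were the same under each of the other scalings, and 3 rose in HFGSC without HF replicate 1, HF replicate 2 or HFGSC replicate 1. Both tested Mageb genes rose in each comparison with HF under every scaling. Calcium-binding S100a genes fell in HFGSC in 6 of 11 cases and in GSC in 9 of 11, with 0 rising in either. Other scalings gave 6 to 7 and 8 to 9 lower genes, and 4 fell in HFGSC without HF replicate 1 or HF replicate 2. Of 5 tested Hoxb genes 4 rose in GSC under every scaling and 2 in HFGSC, where other scalings gave 1 to 2. In HFGSC 0 rose without HF replicate 2 and 1 without any other single array. Between HFGSC and GSC 2 were lower in HFGSC, 0 to 2 under other scalings, 1 without GSC replicate 1 and 0 without any other single array. Of the 6 Magea genes 1 was lower in HFGSC than in GSC, also under every other scaling, with a median log2 difference of -2.64 over the 6. With the replicate block 6 of the Magea genes and 3 of the Hoxb genes were lower in HFGSC than in GSC. Otherwise the counts above stayed within 1 gene with the block.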
